A study of Caenorhabditis elegans with 12 samples.

How the data were processed

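The series holds in situ Hi-C from mixed-stage C. elegans embryos. Nuclei were digested with DpnII and the ends filled in with biotinylated nucleotides before ligation, per the labels' protocols. The 12 genotypes each had 1 deposited set of 3 files, and the series design text gives 2 biological replicates for 5 genotypes, combined in the files, and 1 for the other 7. Reads were mapped to build ce11, per the submitters' processing notes and the bin names. The aligner, the read filters and the balancing tool are not given in the sources used here.

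The deposited contact matrices hold a balanced signal in 2008 bins of 50 kb (355 on X, 302 on I), with equal sums for nearly all bins and with the diagonal and the first off-diagonal at 0. Their totals were 1000000 for 10 libraries, 2000000 for the DCC mutant and 500500000 for rex-47Δ. The last total is what the mean of 2 replicates gives when 1 is scaled 1000 times as high as the other, and then supplies 99.9% of the signal. Read counts cannot be recovered from such values, so no interval for counting error was given.

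The deposited insulation scores are log2 values. Recomputed from the deposited matrices, they matched a square of 10 by 10 bins (500 kb) with r = 1 over X bins for 10 libraries. The deposited score of the DCC mutant matched a square of 5 by 5 bins (250 kb), and that of 6rexΔ correlated at 0.990 with its own matrix (SD of the difference 0.03). The comparison of the DCC mutant with wild type therefore used the 500 kb score recomputed for both libraries, and the mutant was left out of the allele tests at the 8 sites. Its deposited score entered the tests of chromosome I copies as planned, with the recomputed score and its omission as alternatives. The recomputed score is the log2 of the mean contact in the square over the genome-wide mean.

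The deposited z-score matrices hold a score per bin pair, the contact minus a loess expectation at its distance over the loess spread, made with cworld::dekker 0.41.1, per the file headers. For 3 libraries (wild type, 8rexΔ and the DCC mutant) zeros entered the expectation and for 9 they did not, and 5 were made without contacts between chromosomes. The SD of z-scores within chromosomes was 1.41 to 1.47 for the former 3 libraries and 1.20 to 1.27 for the latter 9. As a measure with 1 definition for all libraries, log2 observed over expected was computed from the matrices, the expected value being the mean over X at the same distance.

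Which strain carries which allele came from the genotype labels. The tests, the samples in each, the alternatives and the rule for named loci were fixed before the data were examined, except where a choice is said to have been made after. Because the labels give no coordinates, the planned rule placed each site at the largest rise of the insulation score in the strain that first lacks it over the strain before, keeping the order of sites in the genotype. Where several sites came from 1 difference, local maxima within 3 bins and at least 6 bins apart were taken. No least distance was set between sites placed from separate differences, such as rex-33 and rex-14. A second placement, chosen after the data were seen, took the 8 highest local maxima of DCC mutant minus wild type. On 200 simulated chromosomes with 1600 planted sites, the second rule placed 50.6% of sites within 2 bins at a planted height of 0.1 and 95% at 0.2, and the planned rule 27.5% and 65.3%. At the 8 sites of the second placement, the 8-site class exceeded the yIs187 strain, which was not used to place them, by a mean of 0.11. None of 10000 random sets of 8 X bins had a mean as high (highest 0.06). With the yIs187 strain in place of wild type, 7 of the 8 maxima lay within 2 bins of the same positions. Inserted copies were placed at the largest fall of the score in the carrier, and falls between libraries without a copy were examined after the placements were seen.

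At each site the libraries with and without the deletion were compared by an exact two-sided permutation test over all relabelings of the 11 libraries other than the DCC mutant, with Benjamini-Hochberg adjustment over the 8 sites. At rex-47, where 2 libraries are intact, the smallest p that the test can give is 0.0182. The same kind of test was used for chromosome I copies over all 12 libraries, for contact groups over the 11 libraries, leaving rex-47Δ out of the group with rex-47, and for distance bands over the 8-site and 3-site classes. The scan used limma 3.58.1 (lmFit and eBayes) on the deposited score of 340 X and 1598 autosomal bins. It covered all 12 libraries in 6 classes, with 6 residual degrees of freedom. Benjamini-Hochberg adjustment, at 0.05, was made over the X bins and over the autosomal bins separately. Calls on X and on the autosomes therefore do not share a cutoff in unadjusted p. The scan was tested on simulated data for the contrast of 8 with 3 sites over 340 X bins (20 trials, 20 planted bins per size). It found 48.3% of bins changed by 0.1 and 91% of those changed by 0.2, and 6.07% of its calls were false. The simulated bins varied independently and the changed bins were picked at random, whereas neighbouring bins of the real score share most of their square. These rates therefore need not hold for the real scan.

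X boundaries of wild type were local minima of the score within 3 bins and at least 0.1 deep against the lower flanking maximum within 10 bins. The loci named are the 8 sites, the 6 inserted copies, all wild-type X boundaries, and up to 5 runs of called bins per contrast that lie more than 10 bins from a site or copy, bins up to 3 apart being joined. The run ending at the bin of sdc-2, the called bins on chromosome V and called bins near sites were named after their values were seen. The gene named is the protein-coding gene that spans the bin midpoint, otherwise the nearest one (written as nearest gene), from a table for assembly WBcel235, the sequence of ce11. It names a position and not a target, since a bin is touched by several genes.

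Alternatives covered the score (recomputed with 500 kb or 250 kb squares, averaged over neighbouring bins, centred on the autosomal median or on X), the libraries (each left out in turn, those used for placement left out, the yIs187 strain left out), the boundary depth, the reference, the scan's normalization, test and threshold, the contact measure and the average over bin pairs. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with statmod 1.5.0. Replicates pooled by the authors, the reads, and any X-linked expression or lifespan data were not analysed here.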

Results

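In situ Hi-C was used to measure chromosome folding in mixed-stage Caenorhabditis elegans embryos of 12 genotypes. In this method contacts between chromosomal segments are captured by digesting nuclei with DpnII and ligating the ends that lie close together. In worms with 2 X chromosomes, the dosage compensation complex (DCC), a condensin-containing complex, binds X and lowers its transcription. It is loaded at rex sites (recruitment elements on X). The strains carried deletions of rex sites, extra rex copies at new positions, or loss of sdc-2, the gene whose product brings the DCC to X. With X sites intact there were 2 libraries, wild type and a strain with a rex-32 copy inserted on X (yIs187) and a dpy-27 allele, dpy-27 encoding a condensin subunit of the DCC. Of the deletion strains, 1 lacked rex-47, 4 lacked rex-14, rex-47 and rex-8 (3rexΔ; 3 of these had rex copies on chromosome I), 1 also lacked rex-43, rex-48 and rex-35 (6rexΔ), and 3 lacked these as well as rex-32 and rex-33 (8rexΔ; 2 of these had rex copies on X). The DCC mutant carried an sdc-2 mutation and was fed sdc-2 RNAi bacteria.

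Each genotype had 1 library, so strains that share an allele served as each other's replicates, and the p-values measure the spread among these libraries. The deletions are nested. The same split of libraries therefore served rex-32 and rex-33, another served rex-14 and rex-8, and another rex-43, rex-48 and rex-35. Tests that share a split are not independent, and each compares strains that also differ at the other sites of the split. The contact matrices were balanced and scaled, and their sequencing depth is unknown. Contacts between chromosomes made up 23.3% to 38.1% of each matrix (median 28.2%), with wild type at 37.1%, 6rexΔ at 38.1% and 8rexΔ with rex-32 and rex-8 copies at 36.7%. The insulation score is the log2 ratio of contacts across a 50 kb bin, within a 500 kb square, to the genome-wide mean, so that a low score marks a strong boundary between domains.

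The first comparison asked whether domain boundaries on X depended on the rex sites. Insulation was weaker in the libraries that lacked a site than in those that kept it at 7 of the 8 sites, and the difference passed an exact test at 5. At rex-8 the score was -0.05 ± 0.02 (SD, n = 8) where the site was deleted and -0.26 ± 0.06 (SD, n = 3) where it was intact, a difference of 0.21. The rex-32 region scored 0.03 ± 0.02 (SD, n = 3) without the site and -0.14 ± 0.07 (SD, n = 8) with it. At rex-33 the values were -0.04 ± 0.03 (SD, n = 3) and -0.20 ± 0.09 (SD, n = 8), and at rex-35 they were 0.26 ± 0.02 (SD, n = 4) and 0.16 ± 0.03 (SD, n = 7).

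These tests were exact two-sided permutation tests over the 11 libraries other than the DCC mutant, adjusted by the Benjamini-Hochberg method over the 8 sites. The exact p was 0.00606 at rex-8 and rex-32 (adjusted 0.0121), 0.0182 at rex-33 (adjusted 0.0291) and 0.00303 at rex-43 and rex-35 (adjusted 0.0121). At rex-47 the difference was 0.10 with an exact p of 0.0545 (adjusted 0.0727), at rex-14 it was 0.06 (exact p 0.394) and at rex-48 it was -0.02 (exact p 0.594). The labels give no coordinates for the sites, so they were placed at the largest differences between strains, and the tests partly reuse those strains. Without the libraries that placed each site, 7 sites were still higher when deleted, and 2 passed at an adjusted p under 0.05. The call at rex-33 was lost without wild type (difference 0.14), 8rexΔ (0.16), 8rexΔ with the rex-32 copy (0.14), 8rexΔ with both copies (0.17) or 3rexΔ with rex-47 and rex-8 copies (0.15).

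The DCC mutant, which played no part in that placement, gave a second map of the sites. The 8 highest local maxima of DCC mutant minus wild type along X lay in bins of 50 kb starting at base 3000001 (nearest gene aqp-7, an aquaporin), 6250001 (lro-1), 8000001 (unk-1), 9450001 (gap-2, a Ras GTPase-activating protein), 11050001 (W04G3.5), 13700001 (K11E4.6), 14500001 (nspc-17) and 16700001 (lgc-53, a ligand-gated channel). Taken in order these are rex-32, rex-33, rex-14, rex-47, rex-8, rex-43, rex-48 and rex-35. For 5 of the 8 sites the position was within 2 bins of the first placement. The others were rex-14, first placed at 6.30 Mb beside rex-33, rex-43, first placed at 14.5 Mb, and rex-48, first placed at 14.9 Mb.

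At these positions insulation was weaker without the site at all 8 sites, and 7 passed the exact test. The rex-14 bin scored -0.06 ± 0.03 (SD, n = 8) when deleted and -0.19 ± 0.06 (SD, n = 3) when intact, with an exact p of 0.00606. The rex-48 bin scored -0.06 ± 0.02 (SD, n = 4) and -0.25 ± 0.07 (SD, n = 7), with an exact p of 0.00303, and the rex-43 bin scored -0.04 ± 0.01 (SD, n = 4) and -0.15 ± 0.06 (SD, n = 7), with an exact p of 0.00606. The rex-47 bin scored -0.08 ± 0.05 (SD, n = 9) and -0.17 ± 0.09 (SD, n = 2), with an exact p of 0.0545. It passed with scores centred on X (exact p 0.0182, the smallest this split allows) and without 6rexΔ (difference 0.10) or 8rexΔ with both copies (0.11). Without wild type, which leaves only the yIs187 strain intact, the difference was 0.03. The lowest score without rex-47, -0.18, came from 8rexΔ with both copies. Its rex-8 copy (yIs201) was placed at 9.2 Mb, within reach of the 500 kb square of the rex-47 bin at 9.45 Mb. The effect of that copy on the rex-47 score was not separated. The rex-33 bin did not pass without 8rexΔ (0.16) or 8rexΔ with the rex-32 copy (0.14). At the 7 sites other than rex-47 no library without the site scored as low as any library with it, an outcome that each random relabeling of the libraries has a chance of 0.00303 to 0.00606 of giving. This placement was chosen after the data were seen and uses wild type as its reference. Without wild type 7 sites still passed, and without the libraries that placed the sites first 6 did.

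**Figure D1:**
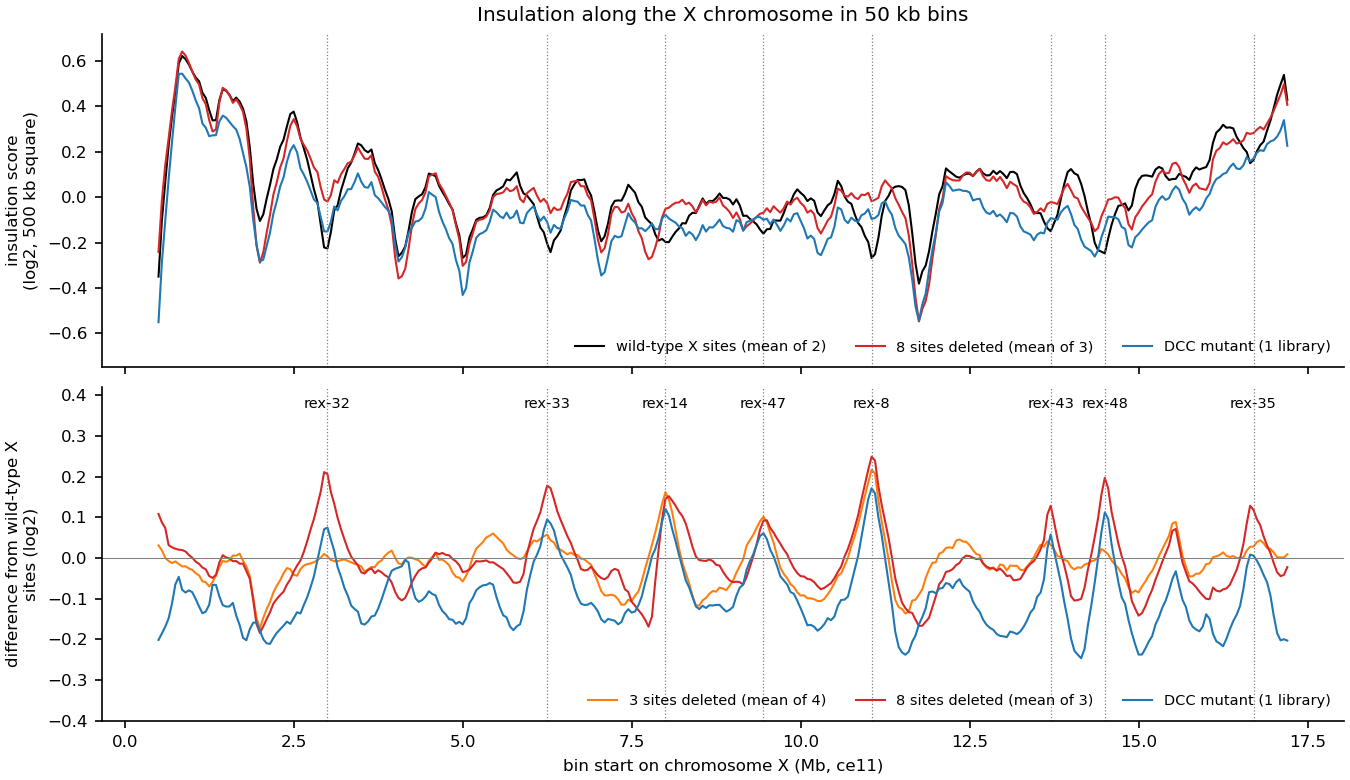
Insulation score along chromosome X in 50 kb bins (top, log2) and its difference from the mean of the 2 libraries with wild-type X sites (bottom, log2), for the mean of the 4 libraries lacking 3 sites, the mean of the 3 libraries lacking 8 sites and the DCC mutant. Dotted lines mark the 8 rex sites as placed from the DCC mutant, where the 8-site class peaks, with its highest peak at rex-8 (0.25 above the libraries with wild-type sites).

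**Figure D2:**
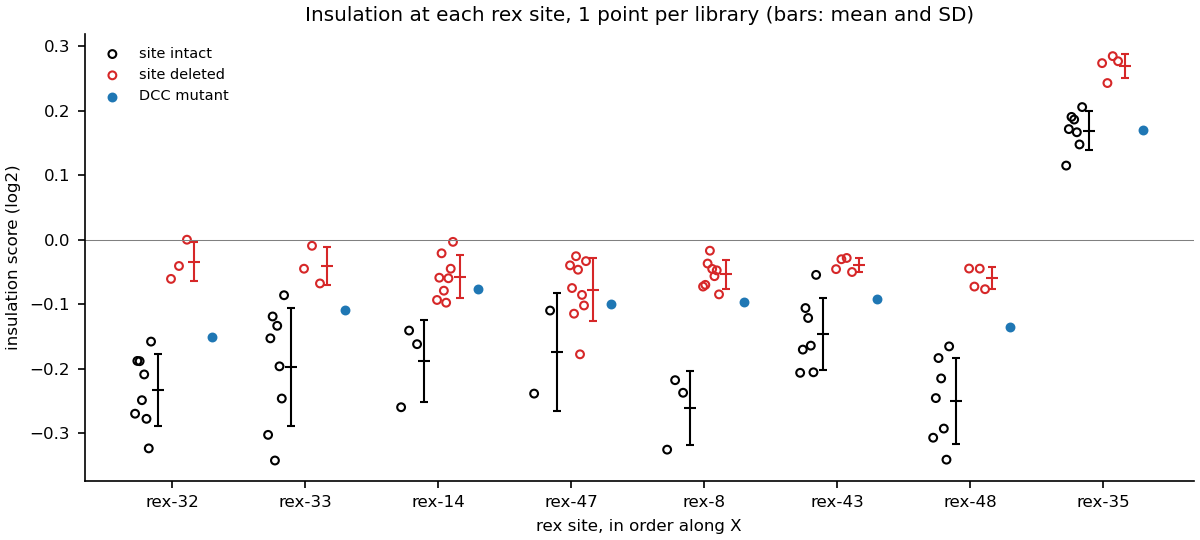
Insulation score (log2) at each rex site as placed from the DCC mutant, 1 point per library, with bars for mean and SD of libraries with the site intact (black) or deleted (red) and the DCC mutant in blue, its score recomputed with the same 500 kb square. Deleted and intact libraries do not overlap at the 7 sites other than rex-47.

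Insulation at rex copies placed at new sites on X was compared with strains of the same deletion class that lacked the copy. The yIs197 copy of rex-32, in the bin starting at base 7800001 (eef-1A.2, a translation elongation factor), scored -0.41 and -0.33 in its 2 carriers and -0.10 in 8rexΔ without it. The yIs201 copy of rex-8, at base 9200001 (vav-1, a guanine nucleotide exchange factor), scored -0.37 in its carrier and a mean of -0.03 in the 2 other 8rexΔ strains. The yIs187 copy of rex-32, at base 15550001 (nearest gene dyn-1, a dynamin), scored -0.01 in its carrier and 0.14 in wild type.

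Each carrier lay below every library without the copy, the DCC mutant left aside. The 9 such libraries spanned -0.18 to -0.08 at yIs197, and the 10 such libraries at yIs201 and at yIs187 spanned -0.16 to -0.01 and 0.11 to 0.18. The order held with the score recomputed from the matrices, averaged over neighbouring bins or centred on X. No test was planned for these copies, which had 1 or 2 carriers each, and none was run. Each copy was placed at the largest fall in 1 carrier, so a low score there is partly built in, and only the second carrier of yIs197, at -0.33, played no part in its placement. The falls that placed yIs197 (0.31) and yIs201 (0.32) were deeper than any in the same windows between the 12 ordered pairs of libraries lacking 3 sites, at most 0.15 and 0.10. For yIs187, searched along all of X, 2 of these pairs had a fall as deep as its 0.15, so its place is uncertain. The first placement left no window for yIs197 between rex-33 and rex-14, so the windows came from the DCC mutant.

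**Figure D3:**
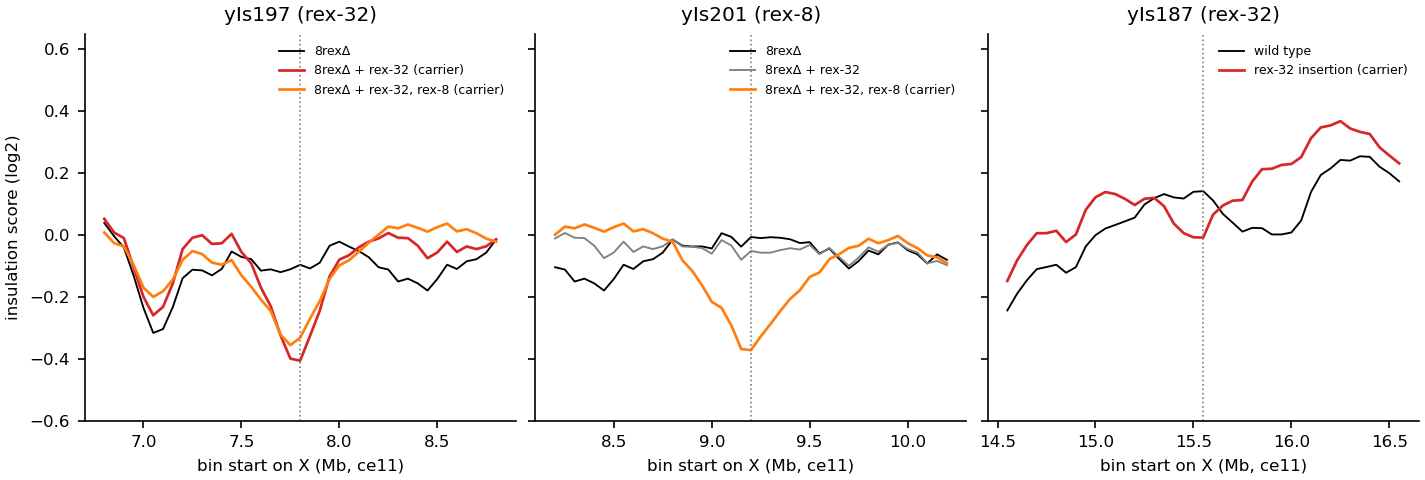
Insulation score (log2) within 1 Mb of each rex copy inserted on X, with carriers in colour and strains of the same deletion class without the copy in black or grey. The dotted line marks the bin where the copy was placed, where carriers of yIs197 score -0.41 and -0.33 and the carrier of yIs201 scores -0.37.

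On chromosome I, which lacks the DCC's normal loading sites, rex copies gave no difference that passed a test. The bin placed for the yIs190 copy of rex-47, starting at base 1300001 (dapk-1, a death-associated protein kinase), scored 0.22 ± 0.12 (SD, n = 3) in carriers and 0.33 ± 0.10 (SD, n = 9) in other libraries, a difference of -0.11 with an exact two-sided p of 0.114. The others include the deposited score of the DCC mutant, made with a 250 kb square, and without it the difference was -0.10 (exact p 0.164). The yIs192 copy of rex-8, placed at base 10150001 (nearest gene fath-1), scored -0.39 ± 0.02 (SD, n = 2) and -0.39 ± 0.04 (SD, n = 10), with an exact p of 0.955. The yIs196 copy of rex-14, placed at base 400001 (nearest gene C07F11.2), scored 0.54 in its carrier, inside the range of 0.54 to 0.67 of the 11 others.

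A fall as deep as the one that placed yIs190 occurred in 26 of 56 ordered pairs of libraries other than the DCC mutant without a copy on chromosome I, so these placements are uncertain. Without the library used to place yIs190 and its reference, the difference was -0.05 (exact p 0.422), and without 8rexΔ with a rex-32 copy, which had the lowest score there among strains without the insertion, it was -0.14 (exact p 0.0182).

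Loss of the DCC was compared with wild type at the rex sites and at the other X boundaries, with the score recomputed from both matrices in a 500 kb square. At the positions placed from the deletion strains, which do not use the mutant, the mutant scored higher than wild type at 7 of the 8 sites. The mean difference over all 8 was 0.10, from -0.13 at rex-48 to 0.22 at rex-8. In this placement rex-33 and rex-14 are adjacent bins and so are not separate boundaries, and rex-48 lies 8 bins from its position from the mutant. Against the yIs187 strain, the other library with intact sites, the mean was -0.01 and 4 of the 8 were higher, with 0.13 at rex-8. The mutant was lower than that strain away from these sites too, by a mean of -0.13 at 10 boundaries. The sites thus exceeded those boundaries by 0.12. Wild-type X had 16 boundaries, of which 8 lay at the sites as placed from the mutant. At the 8 others the mean difference from wild type was -0.11, and 7 of them were lower in the mutant. The lowest were in the bins starting at base 2000001 (Y102A11A.3, -0.18), 5000001 (ZC449.1, -0.16), 7050001 (B0403.6, -0.13), 10300001 (acl-5, -0.13) and 11750001 (nearest gene ttx-3, a LIM homeobox gene, -0.13). The boundaries at 15900001 (F31B9.3) and 1300001 (pdk-1, a protein kinase) differed by -0.07 and -0.04, and that at 4050001 (T06F4.1) by 0.01.

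At the positions from the deletion strains, 6 of the 8 differences from wild type exceeded the SD among the 4 libraries lacking 3 sites at the same bin. Against the yIs187 strain, 1 of the 8 differences did. At the positions from the mutant the differences from wild type, 0.04 to 0.22, are high by construction, and the boundaries left over are those without such a rise. Against the yIs187 strain, the mean at those positions was 0.04 with 6 of 8 higher. There was no test with 1 library each, and the mutant alone was grown on RNAi bacteria. The yIs187 strain alone carried the dpy-27 allele, and the effect of this allele on the comparisons with that strain was not separated. The mutant's mean score over X differed from that of wild type by -0.06, against 0.01 to 0.08 for the other 10 libraries, and centred on X the 8 other boundaries differed by -0.05.

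A scan of all scored X bins asked where insulation changed between deletion classes. Between strains lacking 8 and 3 sites, 9 of 340 X bins were higher and 0 were lower in limma at an adjusted p under 0.05. Of these, 8 bins lay between 2800001 and 3200001 around rex-32, where the score rose from -0.24 to -0.03 (difference 0.20, SE 0.04, limma adjusted p 0.0370), and 1 lay at rex-48 (difference 0.18, SE 0.04, limma adjusted p 0.0454). Between strains lacking 3 sites and those with wild-type sites, 7 bins were higher and 14 lower. The higher bins lay at rex-8 (0.22, SE 0.03, limma adjusted p 0.00202) and rex-14 (0.16, SE 0.03, limma adjusted p 0.0218). Between strains lacking 8 sites and those with wild-type sites, 26 were higher and 21 lower. All higher bins of the 3 contrasts lay within 10 bins of a site or inserted copy, and 8 of 9, 7 of 7 and 25 of 26 within 3 bins, against 193 and 72 of all 340 bins. In the contrasts with wild-type sites this closeness is partly built in, since sites were placed at maxima over wild type.

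Lower scores, meaning stronger insulation, appeared away from the sites in strains lacking 3 sites. The score fell by 0.17 in the bin at 2000001 (Y102A11A.3; SE 0.04, limma adjusted p 0.0205) and by 0.11 in that at 10300001 (acl-5; SE 0.03, limma adjusted p 0.0342). In strains lacking 8 sites it fell by 0.18 in the bin at 2000001 (SE 0.04, limma adjusted p 0.0176). A run of 3 bins from base 11400001 to 11550001 began 7 bins from rex-8, and the score of its last bin, which holds sdc-2 itself, fell by 0.13 in strains lacking 3 sites (SE 0.03, limma adjusted p 0.0368). With scores centred on X, the contrast of 3 sites with wild-type sites had 10 bins higher and 2 lower, and that of 8 sites with wild-type sites had 43 higher and 20 lower. Without the strain carrying yIs187, the first had 12 higher and 0 lower bins and the second 57 and 8. Without wild type, they had 7 higher and 51 lower, and 7 higher and 30 lower, so the balance depended on which library with intact sites was kept. The yIs187 strain also differs from wild type by its dpy-27 allele, whose effect was not separated.

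In the autosomal control, limma called 11 of 1598 bins between strains lacking 8 and 3 sites, where 170 had an unadjusted p under 0.05. All 11 lay on chromosome V between 1850001 and 2600001, with differences up to 0.43, larger than the 0.20 at rex-32. It called 0 in each of the contrasts with wild-type sites, where 273 and 40 autosomal bins had an unadjusted p under 0.05. Of the 340 X bins, 78 had an unadjusted limma p under 0.05 between 8 and 3 sites. In the contrasts with wild-type sites 74 and 99 did. At a threshold of 0.1, the contrast of 3 sites with wild-type sites called 27 autosomal and 37 X bins. For that contrast the lack of autosomal calls at 0.05 does not show that changes were confined to X. The 9 X bins between 8 and 3 sites fell to 0 without 3rexΔ, 3rexΔ with the rex-47 copy, 3rexΔ with rex-47 and rex-8 copies, 8rexΔ with the rex-32 copy or 8rexΔ with both copies. They numbered 41 without 8rexΔ and 14 without 3rexΔ with 3 copies. With the share of contacts between chromosomes as a covariate, the calls fell from 9 to 0 between 8 and 3 sites and from 21 to 6 between 3 sites and wild-type sites, and rose from 47 to 50 between 8 sites and wild-type sites. At the 9 bins the mean difference was 0.16 (mean SE 0.03) without the covariate and 0.15 (mean SE 0.03) with it, where the smallest limma adjusted p on X was 0.0827, and the autosomal calls went from 11 to 13.

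Contacts between the sites themselves were compared between libraries that kept and lacked them. At the positions from the DCC mutant, intact rex-14, rex-47 and rex-8 contacted each other above the level expected at their distance, with a mean log2 observed over expected of 0.39 ± 0.15 (SD, n = 2), against -0.07 ± 0.08 (SD, n = 8) where they were deleted. For rex-43, rex-48 and rex-35 the values were 0.37 ± 0.10 (SD, n = 7) and -0.00 ± 0.03 (SD, n = 4). The pair of rex-32 and rex-33 was below the expected level in either state, at -0.21 ± 0.10 (SD, n = 8) and -0.52 ± 0.14 (SD, n = 3). The DCC mutant had -0.16, 0.02 and -0.32 for the 3 groups.

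The differences were -0.47 (exact p 0.0222), -0.37 (exact p 0.00303) and -0.31 (exact p 0.00606), and each p is the smallest its number of libraries allows. With the deposited z-scores at the positions placed first, the planned test, the differences were -0.96 (exact p 0.0222, adjusted 0.0333), -1.43 (exact p 0.00303, adjusted 0.00909) and -0.27 (exact p 0.206). The first group rests on wild type and the yIs187 strain, and without either no exact p under 0.05 can be reached (planned difference -0.43 without wild type and -1.49 without the yIs187 strain). The z-scores of 3 libraries, wild type among them, were made with another treatment of empty cells.

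**Figure D4:**
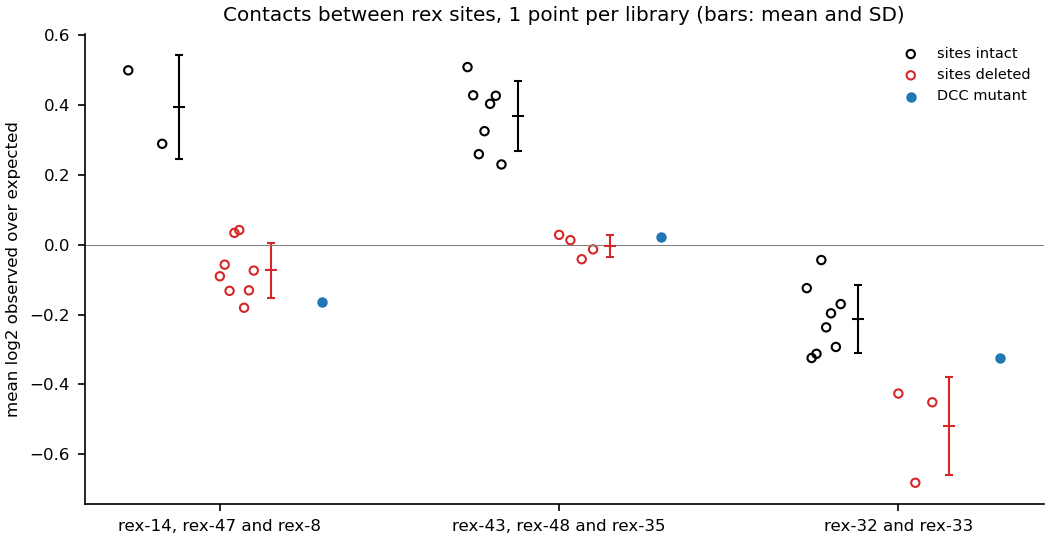
Mean log2 observed over expected contact among the rex sites deleted together, at positions placed from the DCC mutant, 1 point per library, with bars for mean and SD of libraries with the sites intact (black) or deleted (red) and the DCC mutant in blue. Libraries with intact rex-43, rex-48 and rex-35 average 0.37 and those without average -0.00.

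The last comparison asked whether contact frequency by distance on X, relative to the autosomes of the same library, differed between strains lacking 8 and 3 sites. At 0.1 to 0.5 Mb the log2 ratio was 0.03 ± 0.02 (SD, n = 3) and 0.02 ± 0.02 (SD, n = 4), with an exact p of 0.714. At 0.5 to 1.5 Mb the difference was -0.00 (exact p 0.857) and at 1.5 to 4 Mb it was -0.04 (exact p 0.0571). Over 4 Mb it was -0.05 ± 0.02 (SD, n = 3) and -0.01 ± 0.01 (SD, n = 4), with an exact p of 0.0286, the smallest possible, and 0.114 after adjustment over the 4 bands. With these numbers of libraries a change in fewer than 3 bands cannot pass the adjustment, so a change over 4 Mb is left open. In that band wild type had -0.07, the yIs187 strain -0.13, rex-47Δ -0.01 and 6rexΔ -0.09. The ratio thus did not follow the number of deleted sites. Measured on X alone, without the autosomes, the difference over 4 Mb was 0.12 (exact p 0.486). The DCC mutant had a ratio of -0.10 at 0.1 to 0.5 Mb, below the -0.02 to 0.09 of the 11 other libraries, but on X alone its value of 4.75 lay inside their range of 4.63 to 4.97.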

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

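The check described here, a search for a library far from the others of its class, was fixed before the result was seen. It was run on 25 sets of values in classes of 4 or more libraries, some of them at the site positions from the DCC mutant, which were chosen after the data were seen. In 1 set, which does not use those positions, the gap between a library and its neighbours passed Dixon's critical value, where chance gives 1.25. Among the 4 strains lacking rex-14, rex-47 and rex-8, the strain with all 3 copies on chromosome I had a log2 ratio of X to autosomal contacts of 0.0579 at 0.1 to 0.5 Mb, and the other 3 strains had 0.01 each.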

How the results depend on the processing

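The alternatives with sites placed from the DCC mutant, centring on X, the share of contacts between chromosomes as a covariate, the yIs187 strain as reference, the planned sites in the DCC comparison and z-scores made without zeros were chosen only after the data were seen, and the others were planned. For 40 results there were 592 alternative values, of which 493 kept their direction and their side of the threshold (or stayed within the spread), 37 no longer passed, 9 newly passed, 16 changed sign and 37 moved. Where a cause is not named, the cause was not tested. At the positions from the DCC mutant, all 160 alternative values of deleted minus intact lay above 0, from 0.03 to 0.30, and at the planned positions 134 of 152 did. Depth is unknown, which limits every comparison.

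Of the 8 sites, 5 passed as planned, 2 without the libraries used for placement and 0 when only the class that first lacks a site was compared with the class before it, which holds too few libraries to pass, and 4 to 5 when each library was left out. At the positions from the DCC mutant 7 passed, 0 in that comparison and 6 to 8 with each library left out. The planned rex-48 difference, -0.02, became 0.059 there and 0.19 at the position from the DCC mutant. The yIs190 difference on chromosome I was -0.15 to -0.045 when each library was left out, and it passed only without 8rexΔ with a rex-32 copy (-0.14). The yIs192 difference of -0.00 was -0.013 to 0.0095 with each library left out and 0.015 without those that placed it. The gap between rex sites and other boundaries in the DCC mutant, 0.24 at sites chosen for a high value, was 0.30 with deposited scores, 0.21 against the yIs187 strain, 0.16 at the planned sites and 0.12 with both changes.

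For contacts by z-score at planned positions, leaving out each library gave -1.49 to -0.43 for rex-14, rex-47 and rex-8 -1.50 to -1.33 for rex-43, rex-48 and rex-35, and -0.41 to -0.11 for rex-32 and rex-33, the last 2 groups keeping their side of the threshold. The first group did not pass without wild type or the yIs187 strain, which leaves 1 intact library. The pair of rex-32 and rex-33 newly passed as log2 observed over expected (-0.11), averaged over 3 by 3 bins (-0.40) and at the positions from the DCC mutant (-0.68). At those positions the first group had a range of -0.57 to -0.36, and it did not pass with z-scores made without zeros (-1.15), which also leaves 1 intact library. For distance bands, leaving out each library gave -0.0066 to 0.0079 at 0.5 to 1.5 Mb and -0.043 to -0.028 over 4 Mb, where fewer libraries cannot pass. On X alone, without the autosomes, the differences were -0.083, 0.023, -0.0046 and 0.12 in the 4 bands from short to long distances, and with medians they were 0.016 at 0.5 to 1.5 Mb and -0.021 over 4 Mb.

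In the scan between 8 and 3 sites, 9 X bins became 0 at a threshold of 0.01, 14 at 0.1 and 0 with the covariate, and 0 to 41 when each library was left out. They were 41 without 8rexΔ, 14 without 3rexΔ with 3 copies, and 0 without 3rexΔ, 3rexΔ with the rex-47 copy, 3rexΔ with rex-47 and rex-8 copies, 8rexΔ with the rex-32 copy or 8rexΔ with both copies. Between 3 sites and wild-type sites, 21 bins became 2 at 0.01, 37 at 0.1, 33 with quantile normalization, 6 with the covariate and 12 centred on X. The same contrast gave 58 without wild type, 32 without 8rexΔ, 12 without the yIs187 strain, 7 without 3rexΔ, 3 without 3rexΔ with the rex-47 copy and 2 without 3rexΔ with rex-47 and rex-8 copies. Between 8 sites and wild-type sites, 47 bins became 6 at 0.01, 71 without 8rexΔ, 22 without 8rexΔ with both copies, 10 without 8rexΔ with the rex-32 copy, and 50 with the covariate.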

Other observations

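Of the tests below, those of the boundaries away from the rex sites, of the yIs190 copy and of all 28 pairs of sites were chosen only after the results were seen. Between sites of different groups, as deleted together, some contacts were higher with wild-type sites. The contact of rex-33 with rex-14, 1.75 Mb away, had a log2 observed over expected of 0.68 in wild type and 0.43 in the yIs187 strain, against -0.10 ± 0.09 (SD, n = 4) in strains lacking 3 sites and -0.27 in the DCC mutant. In wild type it was the highest of the 21 pairs between groups. Of these, 14 lay above 0 in wild type and 12 in the yIs187 strain. In the mean of strains lacking 3 sites 15 were lower than in both libraries and 3 higher, and in that of strains lacking 8 sites 11 were lower and 6 higher. In the DCC mutant 11 were lower and 7 higher. Chance alone also places pairs below or above both libraries, and the number expected was not computed. The contact of rex-33 with rex-43 was among the higher ones, at 0.21 ± 0.12 (SD, n = 4) in strains lacking 3 sites against 0.06 and 0.11 in the libraries with wild-type sites, and no test was run. Over all 28 pairs, the 7 within groups included, wild type averaged 0.15, above 99.7% of 1000 sets shifted along X, and the yIs187 strain 0.08, above 91.8%. The shifts were drawn with repeats along the 355 bins of X, and neighbouring shifts overlap, so the sets are not independent. The positions were also placed with wild type as reference. The strains lacking 8 sites averaged -0.07 and the DCC mutant -0.06. The pairs of rex-32 with the 7 other sites all lay below 0 in wild type, from -0.47 with rex-43 to -0.12 with rex-33.

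A hypothesis written before its test was run was that a rex copy at a new place contacts other rex copies on its chromosome. In the strain with yIs187 the mean log2 observed over expected between the copy and the 8 sites was 0.15, and the 10 other libraries, the DCC mutant left aside, spanned -0.11 to 0.10 at the same bins. The carrier lay above all 10 with the sites nearest to the copy, at 0.50 with rex-48, 0.28 with rex-43, 0.28 with rex-35 and 0.15 with rex-8, where the highest of the others had 0.01, 0.11, 0.06 and 0.11. It did not with rex-32, rex-33, rex-14 or rex-47. With rex-33 it lay above the mean of the others (0.32 against 0.23). It lay below that mean with rex-32 (-0.65 against -0.31), rex-14 (0.24 against 0.26) and rex-47 (0.10 against 0.15). In the strain with both yIs197 and yIs201, which lacks all 8 sites, the contact between the copies was 0.47, and the 10 other libraries spanned -0.34 to 0.07. Higher contacts were thus seen between yIs197 and yIs201, and between yIs187 and the sites nearest to it, in 1 library for each test. The bins of yIs187 and yIs201 were placed in these same carriers, and the place of yIs187 is uncertain.

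A pattern of interest was the lower score of the DCC mutant at 7 of the 8 X boundaries away from the rex sites. These are the boundaries left after the highest differences were taken as sites, which lowers their mean, and away from the planned sites 10 boundaries had a mean of -0.06. Over these boundaries the mutant differed from wild type by -0.11 and the 10 other libraries by -0.09 to 0.06. The mutant lay -0.019 from the lowest of them, less than their SD of 0.04. By that measure, the test of whether the wild-type library alone accounts for the pattern could not decide. Wild type itself lay inside the range of the 10 libraries. Against the yIs187 strain the mutant was lower at 8 of the 8 boundaries, by a mean of -0.17. That strain was, however, the highest of the 10 libraries at these boundaries (0.06 above wild type). Centred on X, all 10 lay below wild type, by -0.13 to -0.01. Whether the wild-type library alone accounts for the pattern is therefore left open. A lower score of the mutant over the whole of X remains open too. With scores centred on X the mean difference was -0.050, inside the range of -0.13 to -0.01 of the 10 other libraries, so a shift along all of X may account for the pattern. Growth on RNAi bacteria, which only this library had, is an untested alternative.

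The strain with the yIs190 copy alone had a recomputed score of 0.10 in the bin at 1300001 on chromosome I, below all libraries without a copy there, a possible boundary. A boundary in every carrier was not seen, since 0 of the 2 other carriers, at 0.29 and 0.31, lay below the libraries without a copy, which spanned 0.12 to 0.43. Differences between libraries could give a fall of this size, since 26 of 56 ordered pairs without a copy had a fall as deep. No biological explanation for a difference between the carriers was tested.

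Wild type, 6rexΔ and 8rexΔ with rex-32 and rex-8 copies had 36.7% or more of their contacts between chromosomes and values of 1.56 to 1.95 on the first component of autosomal insulation, and the 9 other libraries had shares up to 32.1% and values of -1.51 to 0.36. Whether autosomal insulation follows this share cannot be told apart from other differences of these 3 libraries, because they form a separate cluster. The test fixed in advance, Spearman's rho over the 12 libraries, gave 0.497 (permutation p 0.104). Pearson's r over all 12 was higher and passed its permutation test, but it measures the gap between the clusters, so its value is not given as a relation. Within the 9 other libraries, r was -0.297 (permutation p 0.435) and rho -0.183 (permutation p 0.643).

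For the scan of X bins between strains lacking 8 and 3 sites, the real grouping called 9 bins and was the only 1 of the 35 splits of the 7 libraries to call as many. The highest of the other splits called 8. A share of 1 in 35 lies under the 0.05 fixed in advance. It is also the smallest that these splits can give, and it rests on a margin of 1 bin. The splits therefore cannot exclude that chance assignment gave these calls. On the autosomes the real grouping called 11 bins and another split called 15.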
